A study of Mus musculus with 8 samples.

How the data were processed

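Anti-FLAG ChIP-seq and input libraries came from female mouse F1-2.1 embryonic stem cells with a Tet-on transactivator and an inducible FLAG-tagged GLI1 or GLI2 transgene. Cells grew on irradiated mouse embryonic fibroblasts, which were settled away at harvest, per the labels' protocols. They were kept for 72 hours with 1 µg/mL doxycycline and 100 nM SAG (day 0), fixed with formaldehyde and sheared, and chromatin was pulled down with anti-FLAG agarose, per the labels' protocols. The 8 samples were grouped by their titles into GLI1 ChIP, GLI1 input, GLI2 ChIP and GLI2 input, with 2 replicates each. The titles give the replicate numbers.

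Bases were called with CASAVA 1.7 and reads were aligned with BWA to mm9, per the submitters' processing notes. The peak caller is not given in the sources used here. Per the labels, each ChIP library had its own peak list, named with a cutoff of 1e-4 for GLI1 and 1e-5 for GLI2, and with a setting s of 50 for replicate 1 and 20 for replicate 2. What s stands for is not given in the sources used here. Lists of replicates 1 and 2 were therefore made differently, and so were lists of GLI1 and GLI2. The files held no header. They gave chromosome, start, end, a segment name and a score per peak, and each was matched to the ChIP sample whose title names its factor, day and replicate. All starts and ends were multiples of 200 bp, the narrowest peak was 1000 bp wide and the smallest gap was 1200 bp.

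The score of each peak is the authors' deposited value, and its unit is not given in the sources used here. In replicate 1 the deposited scores began at 40.014 for GLI1 and 50.003 for GLI2, just above 40 and 50, the values of the labels' cutoffs on the Phred scale. In GLI2 replicate 1 a single score was infinite and was ranked first. Many peaks of a list shared a score: of the 100 most common values, 64 in GLI1 replicate 1 and 80 in GLI2 replicate 1 occurred on a single chromosome. In replicate 2 the deposited score was 0 for 55722 of 55741 GLI1 peaks and 48898 of 48921 GLI2 peaks, and it was not used. The design, fixed before the data were examined, had assumed a score in every list. Replicate 2 peaks were ranked by width instead, with ties in a seeded random order, and replicate 1 peaks by score.

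Lists were compared by overlap of at least 1 bp. Chance was estimated from 1000 circular shifts of the second list within each chromosome, over the span that holds peaks in any list, in steps of 200 bp. Alternatives used 200 shifts. The permutation p was one-sided, and the smallest it can take is 0.000999 with 1000 shifts and 0.00498 with 200. Fold over chance is the observed number of shared peaks divided by the mean over shifts. A region is the union of overlapping peaks, and a consensus region of a factor holds a peak of both its replicates. Values of GLI1 and GLI2 lists were compared with a two-sided exact permutation test, whose smallest p with 2 against 2 is 0.333. Shares carry exact (Clopper-Pearson) 95% intervals and densities Poisson 95% intervals. Peaks are not independent reads, so these intervals describe counting of peaks in a list and not the variation between cultures. Density per chromosome was peaks per Mb of the span that holds peaks, divided by the median of the 19 autosomes.

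The overlap code was tested on simulated lists with the chromosomes and widths of the real ones. Peaks not in common were placed uniformly at random along each chromosome, without the clustering of real peaks. The test therefore checks the code, and not whether shifts give the right chance level for clustered lists. Returned shares are corrected for the share given by shifts. With 0, 10 and 30% of the 42634 GLI1 replicate 1 peaks placed in common, it returned -0.0485, 9.61 and 29.1%. With the 26511 GLI2 replicate 1 peaks it returned -0.0594, 10.1 and 29.5%. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots matplotlib 3.10.9.

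Regions named in the text were chosen by a rule fixed before the data were examined. With no annotation of the build, it takes the 10 highest ranked consensus regions of each factor, where a region's rank is the worse of its percentile ranks in the replicates. The rule also named Tsix, Xist, Gli1, Gli2, Ptch1 and members of 8 gene lists. These lists were hedgehog targets, the X inactivation centre, escapees, pluripotency, early lineage, feeder fibroblast, housekeeping and silent receptor genes. None was tested, because the gene table at hand was of GRCm38.p6 and coordinates of different builds were not mixed. The X inactivation centre, the position of peaks relative to genes and the GLI motif were likewise not analysed here.

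Alternatives fixed beforehand were a reciprocal overlap of 50%, peaks set to 500 bp around their centres, joining of peaks within 500 bp, the better-ranked 50% of each list, lists of equal length, and removal of the widest 1%. Others were covered bases in place of peak numbers, the union of replicates, leaving out each replicate, and comparison within replicate numbers. Shifts of 20 to 200 kb in place of shifts along the chromosome, a score of at least 50 in both replicate 1 lists, and removal of chromosomes 2, 9, X and Y were added after seeing the data.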

Results

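Binding of GLI1 and GLI2, the zinc-finger transcription factors at the end of the Hedgehog pathway, was mapped by anti-FLAG ChIP-seq in female mouse embryonic stem cells of the line F1-2.1. Each factor carried a FLAG tag and was expressed from a doxycycline-inducible transgene. The undifferentiated cells (day 0) had received 1 µg/mL doxycycline for 72 hours, together with 100 nM SAG, an agonist of Smoothened that switches the pathway on. The series asks where Hedgehog signaling meets Tsix, the antisense repressor of Xist, when X inactivation starts. The 8 libraries comprised 2 ChIP and 2 input libraries per factor, and the labels call the replicates biological. Each ChIP library had its own peak list in mm9 coordinates. Read counts were not analysed here, so the depth of each library is unknown and the intervals below cover counting error of peaks only. Cells without a FLAG transgene were not analysed here either, so no background peak list stands beside these values. Tsix, Xist, Gli1, Gli2, Ptch1 and all other genes, the position of peaks relative to genes and the GLI sequence motif were not analysed here, because the gene table at hand was of another genome build. Regions are therefore named by chromosome, start and end, counted from 1.

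The first comparison concerned how many sites each factor had. GLI1 peaks numbered 42634 in replicate 1 and 55741 in replicate 2, a mean of 49188 ± 9268 (SD, n = 2). GLI2 peaks numbered 26511 in replicate 1 and 48921 in replicate 2, a mean of 37716 ± 15846 (SD, n = 2). GLI1 thus had 1.30 times as many peaks on average, a difference smaller than the SD of the GLI2 lists (two-sided exact permutation p = 0.667, where 2 lists against 2 allow no p below 0.333). The ratio was 1.61 within replicate 1 and 1.14 within replicate 2. The narrowest peak was 1000 bp wide in all 4 lists. Median widths lay close to this floor, at 1400 bp in GLI1 replicate 1 and 1200 bp in the other 3. Peaks covered 61.2 and 75.9 Mb for GLI1 and 36.5 and 66.9 Mb for GLI2. The labels name a setting s of 50 for replicate 1 and 20 for replicate 2, so each SD also holds that difference in calling. They also name a looser cutoff for GLI1 (1e-4) than for GLI2 (1e-5). When both replicate 1 lists were held to a score of at least 50, GLI1 kept 15877 peaks (37.2%) and GLI2 all 26511. This choice was made after seeing the data. The ratio of the means then turned to 0.949, with the replicate 2 lists still at their different cutoffs.

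Peaks that recurred between replicates made up the smaller part of every list. Of the GLI1 replicate 1 peaks, 20.8% (95% exact interval 20.4 to 21.2) overlapped a GLI1 replicate 2 peak, 3.66 times the 5.69% given by circular shifts along the chromosomes. GLI2 replicate 1 peaks recurred more often, in 34.9% of cases (34.3 to 35.5), 7.07 times the 4.94% given by shifts. The one-sided permutation p was 0.000999 for both, the smallest that 1000 shifts can give. The difference between GLI1 and GLI2 recurrence itself was not tested, and each factor gave a single pair of lists. With equally long lists the shares were 13.8% and 22.7%, and with both replicate 1 lists at a score of at least 50 they were 26.8% and 34.9%, the replicate 2 lists keeping their different cutoffs. Recurrence was higher among peaks with high scores. In the lowest decile of GLI1 replicate 1 scores 13.1% (12.1 to 14.1) recurred, against 37.1% (35.7 to 38.6) in the highest decile. For GLI2 the corresponding shares were 22.9% (21.3 to 24.6) and 52.1% (50.2 to 54.1). The rise was not smooth: GLI2 recurrence dropped to 27.1% in decile 7, below the 34.5% of decile 6. The share that met the replicate 2 list of the other factor also rose, by fewer percentage points. It went from 6.38% to 14.0% for GLI1 and from 8.75% to 16.8% for GLI2. Shifts were not run per decile, and deciles were not adjusted for peak width or chromosome. The rise can therefore not be credited to the score itself. Each of the 9 alternatives kept the excess over shifts, between 3.40-fold and 8.90-fold for GLI1 and between 6.49-fold and 17.6-fold for GLI2, the highest values coming from peaks set to 500 bp around their centres.

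**Figure D1:**
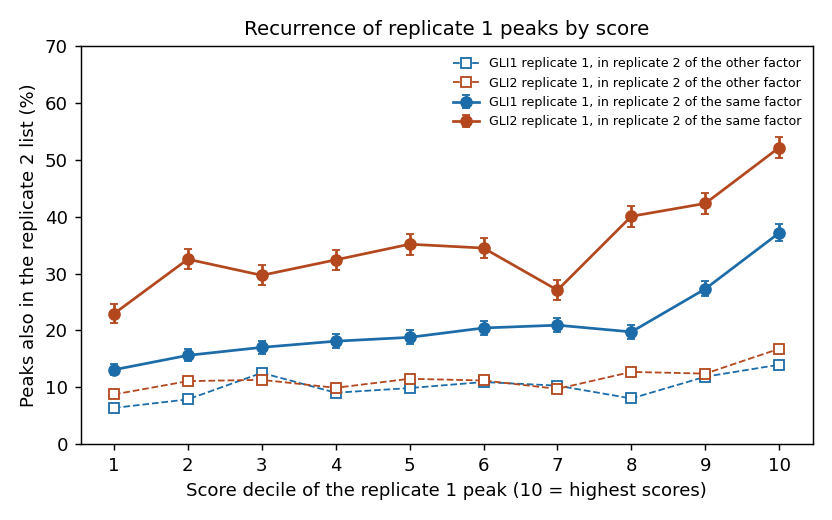
Percentage of replicate 1 peaks that overlapped a replicate 2 peak, by decile of the authors' score (10 is the highest), for GLI1 (blue) and GLI2 (orange). Filled points with exact 95% intervals are for the same factor and rise from 13.1% to 37.1% for GLI1 and from 22.9% to 52.1% for GLI2, and open squares are for the other factor and reach at most 16.8%.

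GLI1 and GLI2 shared few of their recurrent sites, yet more than shifts gave. Merging the replicates left 8869 GLI1 and 9237 GLI2 consensus regions, each with a peak in both replicates, and a median width of 1600 bp. Of the GLI1 consensus regions, 578 (6.52%) overlapped a GLI2 consensus region, against 1.27% by circular shifts, a 5.15-fold excess (one-sided permutation p = 0.000999). Seen from GLI2, 573 regions (6.20%) were shared, 5.08 times the 1.22% by shifts. Of replicate 1 peaks, only 20.8% for GLI1 and 34.9% for GLI2 recurred in replicate 2 of the same factor. Peaks missed in a list would lower the sharing, and cutoffs differed between factors, so the low share does not show different binding. Counted against the separate GLI2 lists, 6.42% of GLI1 consensus regions met a peak in both, 18.3% in a single list and 75.3% in none. Among GLI2 consensus regions the corresponding shares were 6.14%, 20.9% and 73.0%. Over all 6 pairs of lists, covered bases were shared most between replicates of a factor, with Jaccard indices of 8.40% for GLI1 and 12.3% for GLI2. Lists of different factors with the same replicate number followed, at 4.48% and 6.70%, and lists that shared neither reached 3.22% and 4.08%. Overlap of the last kind was still 1.99 to 2.09 times that of shifts. The size of the excess depended on the definition. It was 2.23-fold with the union of replicates, 14.7-fold with peaks set to 500 bp and 10.3-fold with the better-ranked 50% of each list. Without replicate 1 it was 2.86-fold, and without replicate 2 it was 2.95-fold, both between single lists in place of consensus regions.

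**Figure D2:**
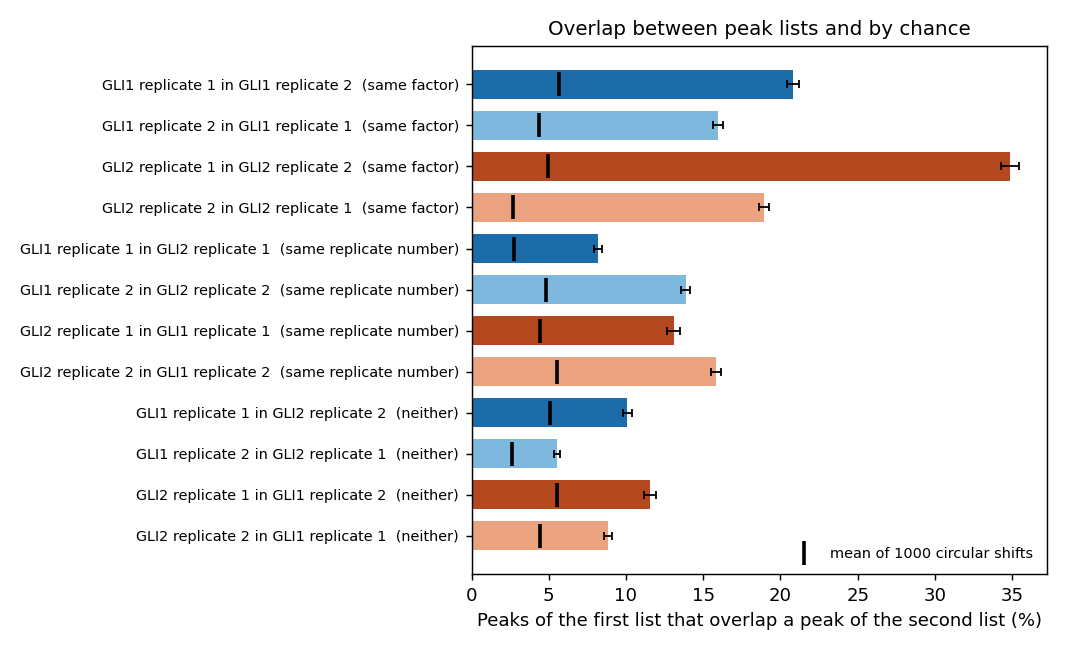
Percentage of peaks of the first list that overlapped a peak of the second by at least 1 bp, for every ordered pair of the 4 lists, with exact 95% intervals; black ticks mark the mean of 1000 circular shifts. Bars of the same factor reach 34.9% for GLI2 replicate 1 in replicate 2, and all bars lie above their ticks.

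The highest ranked consensus regions of the factors were in part the same places. Of the 10 highest ranked GLI1 regions, 6 had a peak in both GLI2 lists, 2 in a single GLI2 list and 2 in none. Of the 10 highest ranked GLI2 regions, 8 had a peak in both GLI1 lists and 2 in a single one. The top GLI1 regions lay on chromosome 9 from 2999401 to 3011400 and from 3014401 to 3039000, with replicate 1 scores of 277 and 408. Next came chromosome 2 from 98501601 to 98508200, with a score of 520, and from 33943001 to 33947200, with a score of 716. These places were also among the top 5 GLI2 regions, where the scores were 343 and 485 on chromosome 9 and 568 and 1021 on chromosome 2. GLI1 regions with no peak in either GLI2 list lay on chromosome 14 from 13183401 to 13187800 (score 114) and on chromosome 4 from 21636401 to 21640400 (score 108). The remaining GLI1 regions began at 46234401 on chromosome 17, 143389001 on chromosome 7, 32366201 on chromosome 6 and 4988201 on chromosome 19, with scores between 91.1 and 99.8. For GLI2, a region of chromosome X from 72100601 to 72104800 ranked sixth, with a score of 497 and a peak in a single GLI1 list. A region of chromosome 14 from 55128601 to 55133000 (score 133) likewise met a peak of a single GLI1 list. Both GLI1 lists had a peak at the GLI2 regions of chromosome 12 from 3106801 to 3111000, with a score of 1208, and from 75902201 to 75906200, with a score of 229. The same held for chromosome 7 from 32238601 to 32243000 (score 163) and chromosome 4 from 150977801 to 150981800 (score 189). Replicate 2 lists carried no usable score, so their part of each rank rested on peak width. The named regions were therefore wide, at 3800 to 24600 bp, against a median of 1600 bp over all consensus regions. Wider regions can meet a peak of another list more often by chance, and shifts were not run for them. How far the sharing of these regions exceeds chance is thus unknown. Enrichment that does not need the tagged protein stays open for the shared places, because cells without a FLAG transgene were not analysed.

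Regions split by factor outnumbered regions split by replicate number. Merging the 4 lists gave 142067 regions, of which 81.1% had a peak in a single list and 598 (0.421%) in all 4. Both GLI1 lists and no GLI2 list had a peak in 6677 regions, and both GLI2 lists and no GLI1 list in 6741. The counts lay further apart with both replicate 1 lists at a score of at least 50, at 3098 and 7231, and with equally long lists, at 2809 and 4863. Together these 13418 regions were 2.05 times the 6547 regions that split by replicate number, of which 1686 were in the replicate 1 lists and 4861 in the replicate 2 lists. The crossed split, GLI1 of one number with GLI2 of the other, gave 2790 regions. The factor split was the largest of the 3 ways to divide 4 lists into pairs, a place that has a permutation p of 0.333, the smallest possible here. It is also a split by cutoff, 1e-4 for GLI1 and 1e-5 for GLI2. With both replicate 1 lists at a score of at least 50, the ratio to the replicate split was 1.69. Most peaks did not recur between replicates, so a region called factor-specific here may still be bound by the other factor. Regions of both factor-specific kinds had a median width of 1600 bp. The count fell to 5227 with the better-ranked 50% of each list and to 7672 with equally long lists, and the ratio to the replicate split was then 2.15 and 2.52. Leaving out a list counts regions of a single remaining list as specific, and gave 54109 without GLI1 replicate 1, 44051 without GLI1 replicate 2, 45702 without GLI2 replicate 1 and 28794 without GLI2 replicate 2.

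The X chromosome, the subject of the series, carried fewer peaks per Mb than most autosomes for both factors. It held 4.71% (95% exact interval 4.52 to 4.92) and 5.22% (5.04 to 5.41) of GLI1 peaks in replicates 1 and 2. Of GLI2 peaks it held 4.29% (4.05 to 4.54) and 5.58% (5.37 to 5.78), while X made up 6.35% of the span of X and the autosomes. Peak density on X divided by that of the median autosome was 0.742 ± 0.0881 over the lists of both factors (SD, n = 4), and X ranked among the 3 lowest of 20 chromosomes in every list. GLI1 and GLI2 did not separate, at 0.749 ± 0.0801 and 0.735 ± 0.129 (SD, n = 2; two-sided exact permutation p = 1). GLI1 minus GLI2 was 0.0494 within replicate 1 and -0.0197 within replicate 2, smaller than the SD of the lists. It was -0.0763 without GLI2 replicate 1 and 0.106 without GLI2 replicate 2. Chromosome 2 (0.663 ± 0.148, SD, n = 4) and chromosome 9 (0.637 ± 0.159) were also low, and varied more between lists. Factor-specific regions were equally frequent on X, with 289 of 6677 (4.33%) for GLI1 and 286 of 6741 (4.24%) for GLI2. Their odds ratio was 1.02 (95% interval 0.861 to 1.21, Fisher's exact p = 0.831).

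**Figure D3:**
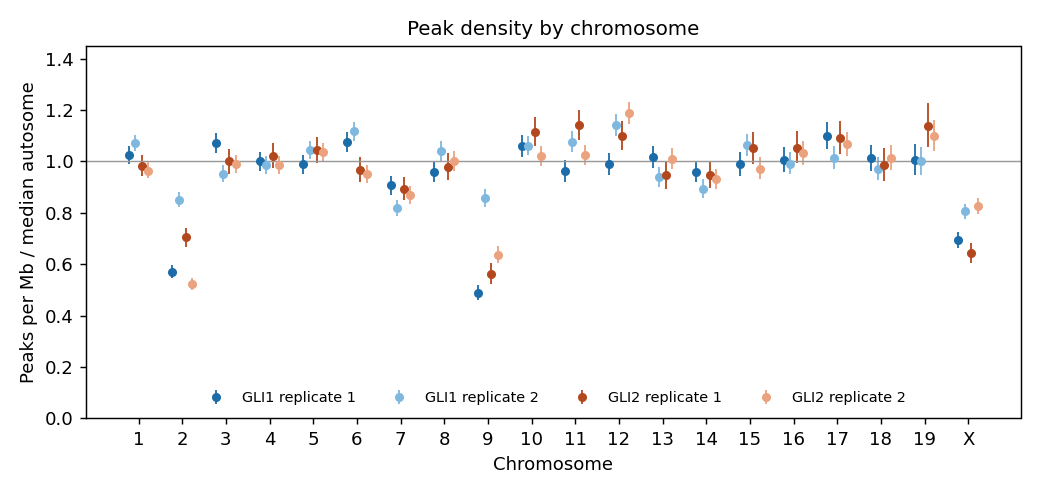
Peaks per Mb of each chromosome divided by the median autosome of the same list, with Poisson 95% intervals for counting error, for the 4 lists. X lies between 0.643 and 0.826, chromosome 2 between 0.523 and 0.852 and chromosome 9 between 0.488 and 0.857.

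Regions found in more lists lay less often on X when all combinations of lists were pooled. X held 5.48% (5.35 to 5.62) of regions seen in a single list, 4.63% (4.36 to 4.91) of those in 2, 3.00% (2.46 to 3.62) of those in 3 and 1.67% (0.805 to 3.05) of those in all 4. Combinations differed: among regions in 2 lists the share ran from 2.85% for the replicate 1 lists of both factors to 6.34% for the replicate 2 lists of both, above the 5.42% and 6.14% of regions in a single replicate 2 list. The 10 X regions with a peak in all 4 lists began with 42132201 to 42138000, 49203601 to 49206600 and 61265201 to 61267000. They continued with 87180601 to 87184000, 96445001 to 96448800, 104637201 to 104640600 and 105032001 to 105033800. The last 3 lay at 107288201 to 107290000, 108803401 to 108807800 and 112014401 to 112016000. Whether any of these lies in a gene was not analysed here.

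A domain of chromosome 11, chosen after its values were seen because it held the widest peak of any list, was densely covered for both factors. Between 19700001 and 20000000, GLI2 replicate 1 peaks covered 55.8% of bases, 39.5 times the coverage of the genome, with peaks from 19758401 to 19819200 and from 19831001 to 19931000. GLI2 replicate 2 covered 29.7% there with 24 peaks. GLI1 replicate 1 covered 47.5% with 17 peaks, up to 36.2 kb wide, and GLI1 replicate 2 covered 15.1% with 24 peaks. The smallest of these shares, in GLI1 replicate 2, was 5.12 times that of the genome. The widest peak belonged to GLI2 replicate 1, so the high coverage in that list follows from the choice of window. Whether the coverage in any list needs the tagged protein is unknown, because cells without a FLAG transgene were not analysed.

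**Figure D4:**
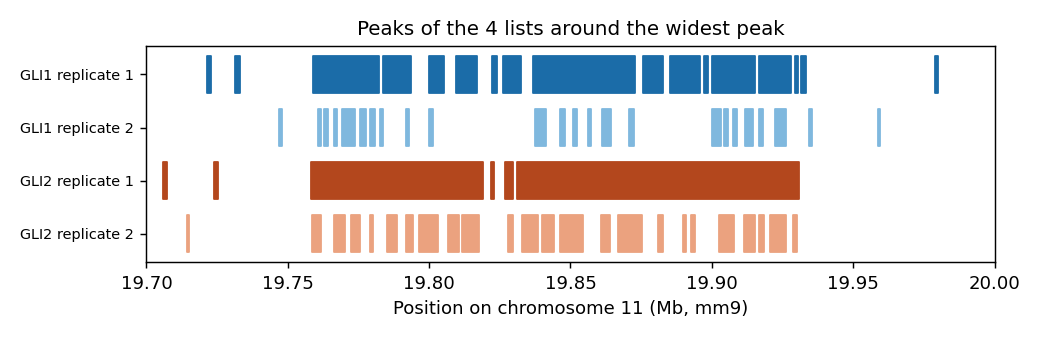
Peaks of the 4 lists on chromosome 11 between 19.7 and 20.0 Mb (mm9), each peak drawn to scale as a bar. GLI2 replicate 1 covers 55.8% of the window in 6 peaks, and the other lists cover between 15.1% and 47.5% of it in 17 or 24 peaks.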

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

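The overlap with circular shifts and the setting of peaks to 500 bp were fixed before the data were examined, and the local shifts, the bounds on each fold and the tests on chromosomes 2, 9, X and Y were chosen after the results were seen.

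Peaks on chromosome Y appeared in lists from female cells, outside the chromosomes that were compared: 10 in GLI1 replicate 2 and 6 in GLI2 replicate 2, above the 3 that a count of 0 allows, and 0 in both replicate 1 lists. They lay between 88601 and 2685800, 1 peak of each list overlapped a Y peak of the other, and their density was 0.175 and 0.114 of the median autosome.

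GLI1 and GLI2 consensus regions overlapped 5.15 times as often as circular shifts gave. Regional clustering of peaks was argued against as the whole cause, since shifts of 20 to 200 kb left a 4.48-fold excess (permutation p = 0.00498). Peaks set to 500 bp gave a 14.7-fold excess (permutation p = 0.00498), with 5.64% shared against 0.385% by shifts. That setting cannot decide on peak width as a cause, because shifts keep the width of each peak. A shared replicate number, which goes with a shared caller setting, was argued against as the whole cause by lists that shared neither factor nor number, at 1.99 to 2.09 times shifts (permutation p = 0.000999), though lists of different factors with the same number overlapped more, at 2.86 to 2.96 times. Occupation of the same sites by both factors remains a hypothesis. Enrichment that does not need the tagged protein stays open beside it, because cells without a FLAG transgene were not analysed here.

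Chromosomes 2 and 9 had fewer peaks per Mb than the other autosomes in 3 of the 4 lists, and in GLI1 replicate 2 chromosome 7 lay lower, at 0.818 of the median autosome. Missing or unmappable sequence cannot be told apart from other causes. Chromosome 2 differed 1.63-fold between the lowest and the highest list, but the highest was a single library, GLI1 replicate 2 (0.852, against 0.523 to 0.704 in the others). Cutoffs and settings differed as well. GLI1 against GLI2 gave an exact permutation p of 0.667, and 2 lists against 2 allow none below 0.333 in that test. A background set per chromosome and raised by its highest-scoring segments stays open as well: over 19 autosomes, Spearman's rho between the top score and the density was -0.211 in GLI1 replicate 1 (permutation p = 0.388) and -0.268 in GLI2 replicate 1 (permutation p = 0.265), and how the score was computed is not given in the sources used here. No biological explanation was tested.

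X held 10 of the 598 regions with a peak in all 4 lists, a density 0.244 of the median autosome (95% Poisson interval 0.117 to 0.449). The product of the 4 separate X densities was 0.297, inside that interval, so a lower density in each list by itself may account for the shortage. That is limited support, because the product fell below the interval on other low chromosomes: 2 (0.179, against 0.469, interval 0.290 to 0.717), 7 (0.576, against 1.04, interval 0.740 to 1.42) and 9 (0.150, against 0.429, interval 0.228 to 0.733). Why each list had a lower density on X stays open, and the number of X chromosomes per cell in these cultures was not tested.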

How the results depend on the processing

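Local shifts, the score of at least 50 and the removal of chromosomes 2, 9, X and Y were chosen after seeing the data, and the other alternatives beforehand. The overlap of GLI1 and GLI2 kept its direction and its side of the threshold in 13 of 13 alternatives (2.23 to 14.7-fold over shifts; from GLI2, 2.24 to 14.4-fold), and the overlap of replicates did so in 9 of 9 for each factor. Among the former, leaving out a replicate and the block by replicate number compared single lists in place of consensus regions. The block is the mean of the values without each replicate, so it adds no separate evidence. Joining peaks within 500 bp joined none, since the smallest gap was wider, so it says nothing about stability. The same holds for the score of at least 50 in the overlap of GLI2 replicates, since every GLI2 replicate 1 peak reached it. Relative density on X stayed between 0.705 and 0.775 in 9 of 9 alternatives. The factor split, which is also a split by cutoff, stayed larger than the replicate split in 8 of 8 (1.69 to 2.52 times). The count of factor-specific regions was 5227 with the better-ranked 50% of each list and 7672 with lists of equal length, where fewer peaks entered, and 28794 to 54109 without a single list, where fewer lists had to hold or lack a peak. The ratio of GLI1 to GLI2 peak numbers reversed to 0.949 at a score of at least 50, which removes peaks of GLI1 replicate 1 alone, and was 1.01 to 1.86 without a single list.

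Replicate numbers are shared between factors, but the labels do not say that they mark a common batch. Differences between replicates 1 and 2 in peaks per Mb correlated at r = 0.204 between GLI1 and GLI2 over 2580 windows, which are not independent samples, and same-numbered lists share a caller setting. With the replicate number as a block, the GLI1 and GLI2 overlap was 2.90-fold and the ratio of peak numbers 1.35, with no call changed. That overlap is between single lists of the same number and not between consensus regions. It is the mean of the values without replicate 1 and without replicate 2. The GLI1 minus GLI2 difference on X was 0.0149, which equals the unblocked value by construction. That difference on X had no stable sign, at -0.0763 without GLI2 replicate 1 and 0.106 without GLI2 replicate 2. Under the block, factor-specific regions numbered 75697.5 on average per number, because a peak in a single list of each number sufficed.

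Depth could not be examined, since the lists hold no read counts. Alternatives for the X inactivation centre, the position of peaks relative to genes, gene lists and the GLI motif were not run, because these results needed an annotation or sequence of mm9.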

Other observations

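The regions described next were chosen after their values were seen. Of the 10 highest-scoring peaks of GLI1 replicate 1 and of GLI2 replicate 1, 8 were the same places. Both lists had their highest score on chromosome 13 from 55071401 to 55073600 (1608 for GLI1, infinite for GLI2), followed by chromosome 12 from 3109001 to 3111000 (1111 and 1208) and chromosome 6 from 103598201 to 103600200 (869 and 1145). Peaks on chromosome 9 from 35112001 to 35114000 (818 and 922) and chromosome 18 from 25658201 to 25660200 (518 and 539) were shared as well. All 10 of the GLI1 peaks and 8 of the GLI2 peaks met a peak in each of the 4 lists. Whether these peaks need the tagged protein is unknown without lists from cells lacking a FLAG transgene. Over the 3468 regions that GLI1 and GLI2 replicate 1 shared, the scores were only weakly related (Spearman's rho 0.0784, across regions, which are not independent replicates). These regions had all passed both cutoffs and many peaks shared a score, so the value does not show how alike the lists score peaks in general.

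Windows dense in peaks seldom passed a fixed count in several lists. Windows of 100 kb with at least 8 peaks numbered 19 and 309 in GLI1 replicates 1 and 2 and 9 and 70 in GLI2 replicates 1 and 2. None of the GLI1 windows and 2 of the GLI2 windows recurred in the other replicate. In a list of the other factor, 1 and 3 of the GLI1 windows and 0 and 4 of the GLI2 windows of replicates 1 and 2 recurred. The same count of 8 was applied to lists of unlike length, and shifts were not run. Windows below it could still hold several peaks: those with 10 GLI1 replicate 1 peaks, on chromosomes 17 and 8, held 4 and 6 in GLI1 replicate 2. The low recurrence therefore does not show that clusters differ between lists. The window of chromosome 11 from 3000001 to 3100000 held 9 and 11 GLI2 peaks and 5 and 7 GLI1 peaks. On chromosome 17 from 46900001 to 47000000, GLI2 had 9 peaks in replicate 1 and 8 in replicate 2, and GLI1 had 1 in each. On chromosome 1 from 136000001 to 136100000 the reverse was seen, with 8 and 7 GLI1 peaks and 1 GLI2 peak in each replicate.

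Within the consensus regions, Spearman's rho between the replicate 1 score and the replicate 2 width was 0.0932 over 8869 GLI1 regions and 0.0905 over 9237 GLI2 regions, and between widths 0.126 and 0.155. Score and width are different measures and these regions had all recurred, so the values do not show how well the replicates rank peaks alike.

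A hypothesis formed after seeing the data was that GLI1-specific and GLI2-specific regions may lie in the same neighbourhoods. Of the 6677 GLI1-specific regions, 24.6% had a GLI2-specific region within 50 kb, against 24.1% by circular shifts, which is 1.02 times chance (one-sided permutation p = 0.181), below the 1.5-fold excess set for the hypothesis. Within 100 kb it was 42.6% against 41.1%, an excess of 1.03-fold that shifts seldom reached (one-sided permutation p = 0.019) but that was also below that bound. Within 5 kb the share was 2.83% against 3.56% (one-sided permutation p for a shortfall = 0.000999). Within 10 kb it was 5.48% against 6.16% (one-sided permutation p for a shortfall = 0.00999). The definition partly makes these shortfalls, since the regions cannot overlap.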
